A study of Homo sapiens with 6 samples.

How the data were processed

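The series holds 6 libraries from TC28a2 cells, an immortalised human chondrocyte line. Cells were transfected with a vector that makes the transcription factor KLF4 with an HA peptide tag, or with an empty vector. Per the labels' protocols, cells were fixed with 1% formaldehyde, chromatin was sonicated and bound DNA was recovered with an antibody against the tag or with rabbit IgG. The groups are HA-KLF4 anti-HA ChIP (2 replicates), HA-KLF4 IgG control (1 library), a library labelled empty vector anti-HA ChIP (1 library) and 2 input libraries. The 4 ChIP libraries have peak lists. Input libraries were not analysed here.

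The deposited lists give, for each peak, its ends and summit on GRCh38, a fold enrichment, −log10 p, −log10 q and a score. Per the submitters' processing notes, the tools were BWA, bedtools and MACS2 and the build was hg38, or GRCh38. Versions, settings and the background library used for calling are not given in the sources used here. The authors called peaks per library, since each library has its own list. The fold (a ratio to the background of that library) and the −log10 q are the authors' values, and the score column is the −log10 q on a 10 times larger scale, per the deposited values. The lists stop at a q-value of 0.05. A fold depends on the background and depth of its own library, so folds were used to rank regions and describe them, and not to compare amounts between libraries. Read depth is unknown, and no interval here includes sampling of reads. Poisson and Wilson intervals (95%) cover counting error only.

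From the lists, a shared region was defined as a merged stretch that holds at least 1 peak of each HA-KLF4 replicate with an overlap of at least 1 bp. Its summit is that of its highest peak, and its fold is the mean of both replicates. Shared regions that overlapped a peak of either control were removed. Overlaps and promoter shares were compared with 1000 circular shifts along each chromosome (a permutation of positions), one-sided, for which 0.001 is the smallest p. Analyses by position used chromosomes 1 to 22, X and Y. A promoter was 1000 bp either side of a protein-coding transcription start site in GENCODE release 44 (basic transcripts). Other features were set against 200 shifts, two-sided, for which 0.01 is the smallest p.

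Sequence motifs (19 consensus sequences) were searched on both strands within 50 bp of the summit and in windows of the same length centred 500 bp either side. The window and its left flank were compared as pairs by an exact binomial test on discordant pairs, two-sided. The ratio of that test is given with an exact 95% interval, since many p-values were too small to be represented. Promoter occupancy of 35 gene lists (20 symbol lists and 15 families set by gene name) was compared with all other protein-coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 35 lists and a threshold of 0.05. A logistic model added the GC content and the observed over expected CpG of 1 kb of sequence. This was taken around 1 start site per gene, the canonical one where marked. A gene counted as carrying a region if a summit lay at any of its promoters. A window of 200 bp either side of a summit was called rich in tandem repeats when at least 20% of its words of 10 bp occurred more than once in it.

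The designs, lists, motifs, 19 of the 22 alternatives and the rule for named genes were fixed before the data were examined. That rule named 12 genes whatever their values, the 2 members of each symbol list with the highest mean fold at a promoter, the member with the highest fold of each family that passed its test, the 10 strongest regions and the 5 highest peaks of each control. A gene that this rule chose is not reported here. A further 3 alternatives were chosen after seeing the data: removing regions for IgG peaks alone, counting any overlap with a promoter, and leaving out regions rich in tandem repeats. The analyses of tandem repeats, of strength groups, of small RNA genes and of peak edges at KLF4 were likewise added after seeing the data. The measure of tandem repeats and the word CACCC were picked after the sequences of the strongest regions had been read. The alternatives covered the peak threshold, the overlap rule, equal list lengths, each replicate left out, control removal, promoter width, motif, window and background.

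Functions were tested on simulated data. In copies of the 111486 replicate 1 peaks, a planted overlap of 59.9% was recovered as 59.9%. Of 20000 random sequences, 25.7% carried a planted or chance KLF core and 25.7% were found. Over 19654 genes with equal chances of a region, 98% of raised lists of 40 random genes were called and 0.6% of lists that were not raised. Real lists differ in size and promoter composition, so these rates do not carry over to them. Software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, pysam 0.24.0 and matplotlib 3.10.9.

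Nothing in the labels says that the 2 replicates came from separate cultures, so their spread may be technical. Controls have 1 library each, and 2 libraries against 1 cannot reach p = 0.05 in a permutation test, so no test between groups was made. The KLF4 locus was inspected in each library as a check on the labels. It showed KLF4 exon peaks in the empty vector library, for which the label gives no source. Whether the label is right cannot be told from them, so it is called the library labelled empty vector. The HA-KLF4 and empty vector libraries also carry different run names in the labels, so run and group cannot be told apart.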

Results

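Binding of HA-tagged KLF4 was mapped in TC28a2 chondrocytes. The anti-HA lists held 111567 peaks in replicate 1 (95% Poisson interval 110913 to 112224) and 133206 in replicate 2 (132492 to 133923), which covered 73.9 Mb and 93.1 Mb. The IgG control list held 320 peaks (285.9 to 357.1) over 0.0680 Mb, and the list of the library labelled empty vector held 862 peaks (805.4 to 921.5) over 0.341 Mb. The median fold enrichment was 4.37, 4.64, 6.47 and 6.40 in the same order. Folds are the authors' values, each relative to the background of its own library. The number of reads is unknown, so the lengths of the lists cannot be separated from depth.

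The first comparison asks how far both HA-KLF4 replicates located the same sites. They shared 93715 regions. Peaks of replicate 2 overlapped 95.1% of the replicate 1 peaks, and peaks of replicate 1 overlapped 72.8% of the replicate 2 peaks. Shifted lists gave a mean of 7386 shared regions with a maximum of 9527, and mean overlaps of 7.96% and 6.57% (one-sided permutation p = 0.001 for each of the 3 measures, the smallest possible). Overlapping summits lay a median of 49 bp apart. Across regions, which are not independent replicates, Spearman's rho between the folds was 0.878. The fold was higher in replicate 2 in 85.4% of regions, with a median ratio of 1.26. The SDs of folds given below therefore include a difference between whole lists. At a −log10 q of at least 10 the shared regions numbered 47631.

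The controls ask which regions appear without the antibody against the tag or without the tagged protein. Of 253 IgG peaks on the chromosomes used, 117 (46.2%, Wilson interval 40.2 to 52.4) lay in shared HA-KLF4 regions, against a shifted mean of 4.80% (permutation p = 0.001). This share depended on the rule, at 24.8% for −log10 q of at least 10, 29.2% for summits within 100 bp and 2.37% for a reciprocal overlap of 50%, and it stayed above the shifted mean in each. The last rule could be met by few IgG peaks, whose median width was 118.5 bp against 628 bp for the regions. Of 800 peaks of the library labelled empty vector, 64 (8%, interval 6.31 to 10.1) lay in shared HA-KLF4 regions, against 4.25% (permutation p = 0.001). That overlap was 6.93% with a permutation p = 0.14 at a −log10 q of at least 10. The label of this library is in doubt from its KLF4 peaks, described at the end. Removing 146 regions left 93569 for all that follows, and 93604 remained when IgG peaks alone were removed.

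HA-KLF4 regions were concentrated at promoters. A summit lay within 1000 bp of a protein-coding start site in 16118 regions (17.2%, Wilson interval 17.0 to 17.5), compared with a shifted mean of 2.27% (permutation p = 0.001). Random placement within 100 kb, which keeps the surroundings, gave 4.63% and so a smaller excess. Promoter shares of the control peaks were 14.6% (10.8 to 19.5) for IgG and 3.0% (2.02 to 4.43) for the library labelled empty vector. Coding exons held 3.55% of regions against 1.24% after shifting, and 3' UTRs 2.69% against 1.48%. Introns held 49.7% against 53.6%, and intergenic sequence 24.5% against 39.8% (two-sided permutation p = 0.01 for each feature, the smallest possible). The median summit lay 13.7 kb from the nearest protein-coding start site.

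**Figure D1:**
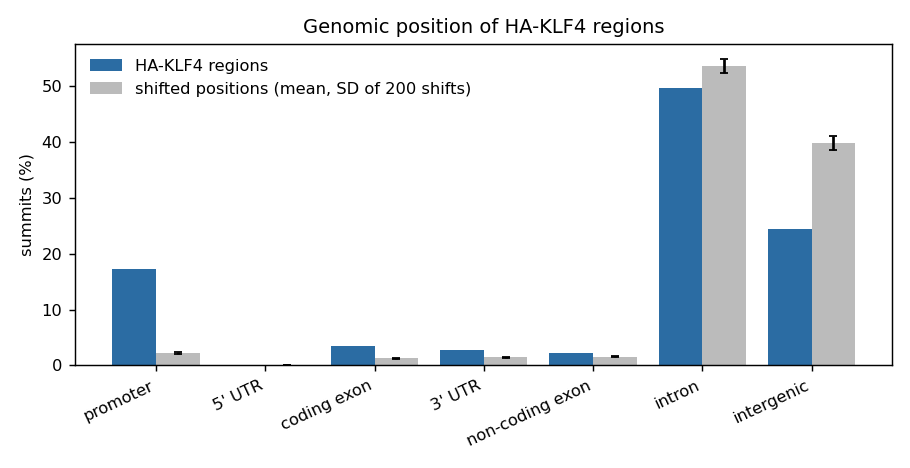
Share of summits (%) by annotated feature for the 93569 HA-KLF4 regions (blue) and for shifted positions (grey, mean with the SD of 200 shifts). Promoters hold 17.2% of regions against 2.26% of shifted positions, and intergenic sequence 24.5% against 39.8%.

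The sequence bound by KLF factors was centred on the summits. The KLF core CCMCRCCC, which takes in the CACC box and the GC box, occurred within 50 bp of 28.7% of summits (28.4 to 29.0) and in 6.94% of flanking windows. It was in the summit window and not the left flank of 24681 regions and the reverse in 4305, a ratio of 5.73 (5.55 to 5.92). Its share was 36.0% at promoters and 27.2% elsewhere. Against shuffles that keep dinucleotides, 10.9% held the core, a smaller excess than against flanks, and the short KLF4 consensus RRGGYGY was at 34.1% of summits and 18.3% of flanks. The GC box CCCCGCCC was at 10.4% of summits and 1.69% of flanks, and the CACC box CCACACCC at 5.86% and 1.48%. In the IgG peaks 3.56% held the core (1.88 to 6.62) against 5.73% of flanks. In the library labelled empty vector 5.12% held it (3.80 to 6.88) against 3.38%.

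Sites of other factors were also above or below their flanks. The AP-1 site TGASTCA, bound by FOS and JUN proteins, occurred at 3.58% of summits outside promoters and 1.47% of their flanks (discordant ratio 2.57, 2.39 to 2.76). At promoters it occurred at 1.32% against 1.12% (ratio 1.18, 0.962 to 1.45, exact test adjusted p = 0.13). The difference between these settings was not tested. The core of the CTCF site was at 1.00% of all summits and 0.232% of flanks (ratio 4.21, 3.63 to 4.89). ETS sites were at 5.24% of promoter summits against 2.41% (ratio 2.23, 1.97 to 2.53). SOX sites were below their flanks, at 1.92% against 2.63% (ratio 0.728, 0.684 to 0.775), as were GATA sites, at 2.84% against 5.75%, and TATA boxes, at 0.280% against 1.12%. The shuffled background was run for the KLF core alone, so base composition was not taken into account for the other sites. It stays open for the SOX, GATA and TATA sequences, which hold more A and T than G and C.

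**Figure D2:**
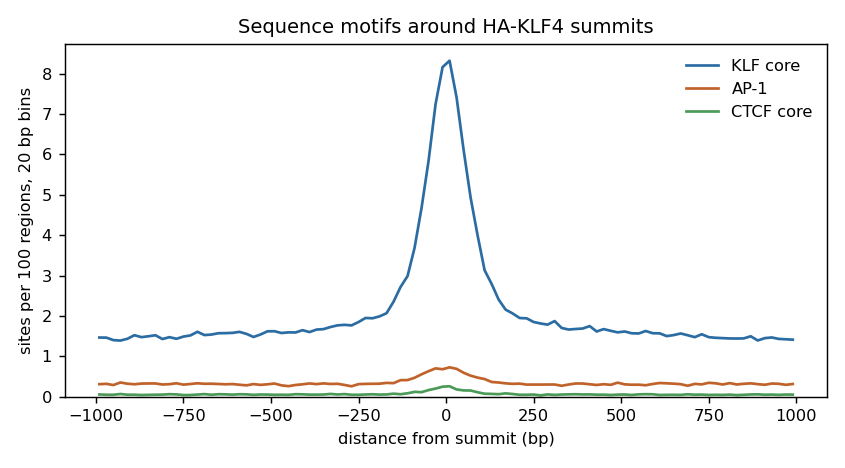
Motif sites per 100 regions in bins of 20 bp, by distance from the HA-KLF4 summit in bp, for the KLF core (blue), AP-1 (orange) and the CTCF core (green). All 3 lines peak at the summit, and the KLF core is the highest, in 28.7% of windows of 50 bp either side.

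Strong and weak regions differed in sequence. Regions were ranked by mean fold and divided into 10 groups of equal size. From the weakest to the strongest group the KLF core rose from 20.4% of summits (19.6 to 21.2) to 46.9% (45.9 to 47.9), while its flanks went from 5.58% to 10.9%. AP-1 went from 5.00% (4.58 to 5.46) to 1.11% (0.918 to 1.34), where the flanks were at 1.14%. GC content of the windows went from 58.3% to 70.7%. Windows rich in tandem repeats made up 2.76% of the weakest group (2.44 to 3.11) and 33.7% of the strongest (32.8 to 34.7).

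**Figure D3:**
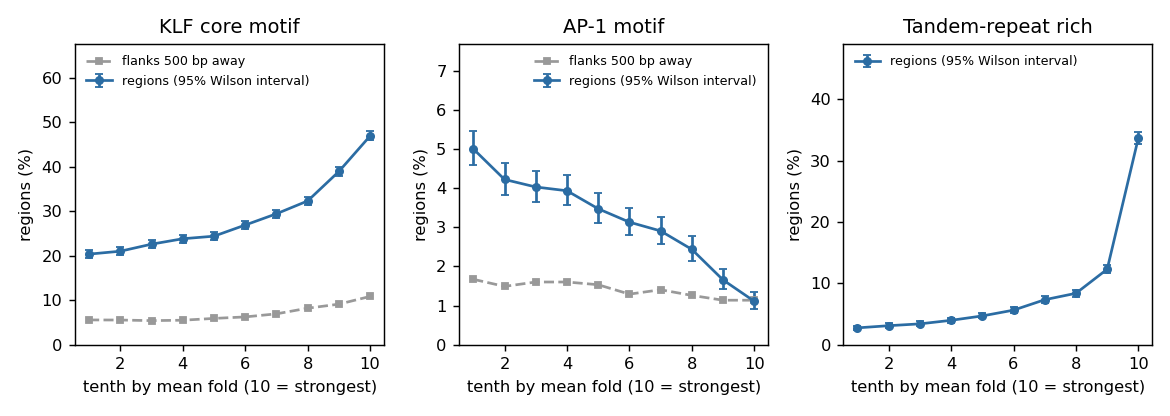
Share of regions (%) with a KLF core, with an AP-1 site and in tandem-repeat rich sequence, by group of mean fold from 1 (weakest) to 10 (strongest), with 95% Wilson intervals, and in grey the flanks 500 bp away. The KLF core goes from 20.4% to 46.9%, AP-1 from 5.00% to 1.11% and tandem-rich sequence from 2.76% to 33.7%.

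Gene lists were compared by the share of genes with a region at a promoter, which held for 14274 of 19654 protein-coding genes (72.6%). By Fisher's exact test, the lists above other genes were TGF-beta and BMP signalling (34 of 36, adjusted p = 0.0093), autophagy and stress defence (31 of 33, adjusted p = 0.016), the circadian clock (16 of 16, adjusted p = 0.027) and housekeeping genes (28 of 28, adjusted p = 0.00088). Families above by the same exact test were ribosomal proteins (82 of 85, adjusted p = 1.5e-07), proteasome subunits (36 of 39) and HOX genes (36 of 39, adjusted p = 0.013 for both), and ZNF-named zinc finger genes (407 of 508, adjusted p = 0.00058). Below other genes by this exact test were the liver markers (8 of 27, adjusted p = 2.8e-05), the blood cell markers (6 of 25, adjusted p = 5.1e-06), olfactory receptors (4 of 381, adjusted p = 3.6e-207) and keratins (13 of 55, adjusted p = 9.5e-13). Several calls depended on the setting. With promoters of 500 bp the exact test gave adjusted p = 0.77 for the circadian list, 0.13 for TGF-beta and BMP signalling and 0.064 for autophagy, and housekeeping genes had 0.054 at −log10 q of at least 5. At that threshold the exact test gave adjusted p = 0.82 for proteasome subunits, 0.64 for ZNF-named genes and 0.079 for HOX genes, and ribosomal proteins had 0.15 at 10 or more. Genes are not independent replicates in these tests.

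Promoter occupancy followed base composition, and part of the calls did not hold with it in the model. Genes were classed by the sequence around 1 start site each. Those with a CpG-rich promoter there carried a region in 11626 of 12803 cases (90.8%, 90.3 to 91.3), and other genes in 2648 of 6851 (38.7%, 37.5 to 39.8). The region could lie at another promoter of the same gene, and the number of start sites per gene was not taken into account. With GC and CpG in a logistic model (n = 19654 genes), 1 of the 6 raised lists that could be fitted stayed above other genes, the ribosomal proteins (adjusted p = 0.015). The odds ratio went from 1.53 to 1.09 for ZNF-named genes and from 5.85 to 1.93 for autophagy. It also fell, but stayed further from 1, for proteasome subunits (4.53 to 3.52), HOX genes (4.53 to 3.09) and TGF-beta and BMP signalling (6.42 to 3.19). For these the lost call alone does not show that composition was the cause. The lower occupancy of the liver list (odds ratio 0.158 to 1.07) and the blood list (0.119 to 0.301) was no longer called either. The 4 lists below in this model (n = 19654 genes) were olfactory receptors (adjusted p = 9.6e-07), keratins (adjusted p = 0.0056), FOX genes (36 of 52, adjusted p = 0.0056) and SOX genes (11 of 19, adjusted p = 0.026). The circadian and housekeeping lists could not be fitted, since each member carried a region.

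Lists tied to cartilage and joint disease did not pass the test. Cartilage matrix genes carried a promoter region at 16 of 30 (exact test, adjusted p = 0.063), chondrocyte transcription factors at 29 of 35, matrix-degrading proteases and inhibitors at 22 of 32 and inflammatory mediators at 24 of 40. KLF and SP factors had 21 of 26, hypertrophy and bone 17 of 24, tendon, ligament and meniscus 20 of 26, synovial lining and fibroblast 17 of 18 (exact test, adjusted p = 0.088), and pain and nociception 15 of 24. Cell cycle and apoptosis had 27 of 31, actin cytoskeleton and YAP targets 22 of 25, epithelial KLF4 targets 16 of 26, pluripotency 13 of 20 and the neuron markers 19 of 25. Among the families not called were collagens (32 of 44), integrins (24 of 30), complex I subunits (32 of 37), WNT ligands (15 of 19), frizzled receptors (9 of 10), FGF ligands (16 of 22) and dual-specificity phosphatases (19 of 24).

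**Figure D4:**
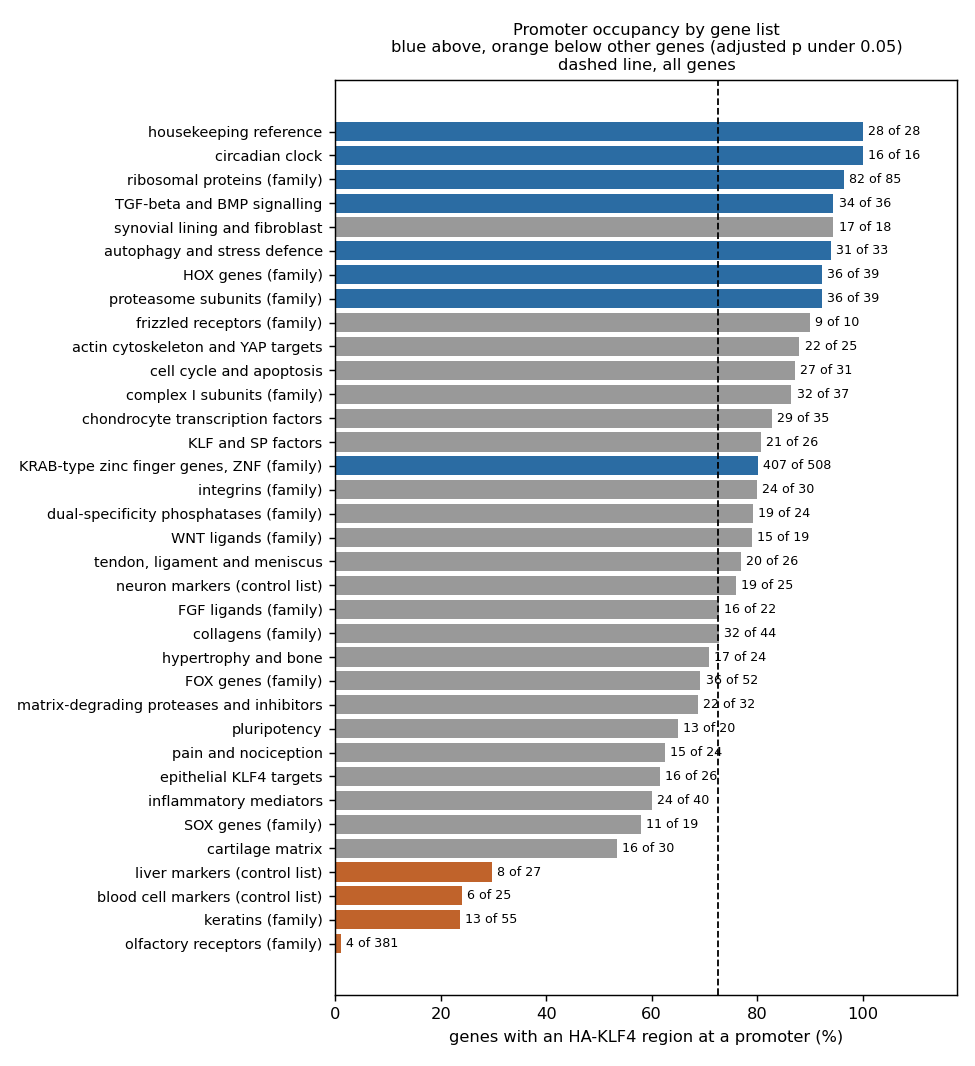
Share of genes (%) with an HA-KLF4 region at a promoter in each of 35 lists, with the counts beside the bars. Blue bars are above and orange bars below other genes at adjusted p under 0.05 by Fisher's exact test, grey bars are not called, and the dashed line is the 72.6% of all genes. Lists run from 4 of 381 olfactory receptors to 28 of 28 housekeeping genes.

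The promoter of ACAN, which encodes the cartilage proteoglycan aggrecan, had the highest fold of the cartilage matrix list, at 19.96 ± 4.51 (SD, n = 2 here and below). Its region spans chromosome 15, 88802692 to 88804119 on GRCh38, with the summit 98 bp upstream of the start site. COL9A3, a chain of collagen type IX, followed at 16.6 ± 3.91. COL2A1, the main cartilage collagen, had 10.8 ± 2.59 (chromosome 12, 48004175 to 48005099). SOX9, the factor that drives chondrocyte identity, had 10.9 ± 2.38 (chromosome 17, 72120353 to 72124401). Its summit lay 879 bp from the start site, so it had no region with promoters of 500 bp. COMP had 6.35 ± 0.997, or 18.1 when promoters reached 5000 bp. PRG4, which encodes the joint lubricant lubricin, had no promoter region. The nearest lay 11331 bp from its start site with a fold of 18.6 ± 5.01. Among the chondrocyte factors, NFATC1 had 14.0 ± 2.62 and PITX1 13.5 ± 4.03.

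Genes of matrix breakdown and inflammation carried regions over a wide span of folds. ADAMTS5, an aggrecan-cleaving protease, had 4.50 ± 0.545, IL6 had 3.75 ± 0.957, PTGS2 (cyclooxygenase 2) had 3.71 ± 1.297 and NOS2 (inducible nitric oxide synthase) had 5.63 ± 0.741. These lie below the median fold at promoters, 6.68. At −log10 q of at least 10 ADAMTS5, IL6 and PTGS2 had no promoter region, and PTGS2 had none at 5 or more. MMP13, a collagenase, had no promoter region, and the nearest was 136514 bp away. In the same lists ADAMTS2 had 11.2 ± 4.01, ADAMTS7 had 10.3 ± 3.26, and the NF-kappaB regulators NFKBIZ and TNFAIP3 had 14.2 ± 3.43 and 11.2 ± 1.78. The highest folds of the KLF and SP factors were at KLF3, 22.6 ± 6.13, and KLF13, 18.7 ± 2.25, and KLF2 had 10.1 ± 2.12. From replicate 1 peaks alone KLF13 had 5.98 and ADAMTS2 2.56, and with promoters of 500 bp KLF13 had 7.501, so these values depend on which summit counts as the promoter. In TGF-beta and BMP signalling CHRD had 19.6 ± 7.06 and BMPR1B 16.6 ± 2.88. In autophagy ULK1 had 16.1 ± 4.46 and MAP1LC3B 13.3 ± 3.93, and in the circadian list RORA had 15.8 ± 1.89 and PER3 10.6 ± 2.01.

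Leading promoters of the remaining symbol lists, picked as the maxima of their lists, were IHH (16.6 ± 4.08) and ALPL (14.2 ± 2.29) for hypertrophy and bone, COL6A2 (16.8 ± 3.18) and TNXB (14.4 ± 2.32) for tendon, and CDH11 (11.8 ± 0.844) and ENG (11.3 ± 1.14) for the synovial lining. NTRK3 (14.1 ± 7.27, from 8.92 and 19.2 in the replicates) stood for the pain list, and CCNE1 (14.0 ± 2.93) and BBC3 (13.1 ± 3.55) the cell cycle list. KRT19 (16.0 ± 4.40) and OVOL1 (15.2 ± 4.30) led the epithelial list, UTF1 (15.7 ± 1.03) and TERT (14.0 ± 3.21) pluripotency, and FLNA (16.0 ± 4.82) and YAP1 (12.8 ± 2.91) the actin list. Leading members of the control lists were ELAVL3 (22.4 ± 6.90), RBFOX3 (22.1 ± 7.09), HBA1 (13.1 ± 4.05), HBA2 (10.1 ± 3.98), APOC3 (10.3 ± 2.08) and APOA1 (9.31 ± 1.07). Housekeeping genes were led by SDHA (12.4 ± 3.64) and TUBB (12.1 ± 2.29). Of the called families, RPS7 had 14.1 ± 1.32, PSMB9 10.6 ± 1.06, ZNF395 16.2 ± 5.41, HOXD13 10.8 ± 3.89 and OR6B3 6.20 ± 0.0789.

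The 10 strongest regions lay away from promoters in tandem repeats. The highest, with a fold of 40.9 ± 12.7 (SD, n = 2), spans chromosome 8, 142988878 to 142991705, 26.9 kb from the start site of LY6E, in an intron of a gene that does not code for protein. In the 200 bp either side of its summit 55.9% of words of 10 bp were repeated, and CACCC occurred 25 times on either strand. The next lay in the 3' UTR of KLHDC4 (40.4 ± 11.8), in an intron of MAD1L1 (40.3 ± 13.0), near ADGRA1 (38.7 ± 11.5) and near KIAA2013 (38.0 ± 11.5). Regions in METRNL, PCGF3, P2RX5 and CBFA2T3 and near ERMARD completed the 10 strongest, at folds of 35.6 to 37.3. Not all were rich in CACCC, which occurred 4 times at KLHDC4 and 1 time at MAD1L1. Of the 200 strongest regions, 171 (85.5%, 80.0 to 89.7) were rich in tandem repeats, against 9% of places 5 kb away. Of those 200, 61% lay within 5 Mb of a chromosome end, as did 23.8% of all regions.

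The KLF4 gene itself was inspected because the cells were transfected with it. It lies on chromosome 9, 107484852 to 107489769, with 5 exons. Replicate 1 had no peak on its exons. Replicate 2 had 4 with a highest fold of 1.53, the IgG control 3 with a highest fold of 7.05 and the library labelled empty vector 3 with a highest fold of 18.9. Peaks covered 99.2%, 98.2% and 100% of coding bases in these 3 libraries, 75.1%, 75.0% and 83.1% of exon bases, and 6.05%, 8.48% and 60.8% of intron bases. Exon 1 had no peak in replicate 2 or the IgG control and was covered in part in the library labelled empty vector. At the 2 long introns, of 1101 and 662 bp, the 4 facing peak edges ran past their exons by 15 to 18 bp in the IgG control, by 241 to 250 bp in the library labelled empty vector and by 0 to 79 bp in replicate 2. KLF4 was the sole gene with 2 or more exons under peaks in either control. The nearest HA-KLF4 region outside control peaks was 138093 bp from its start site.

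**Figure D5:**
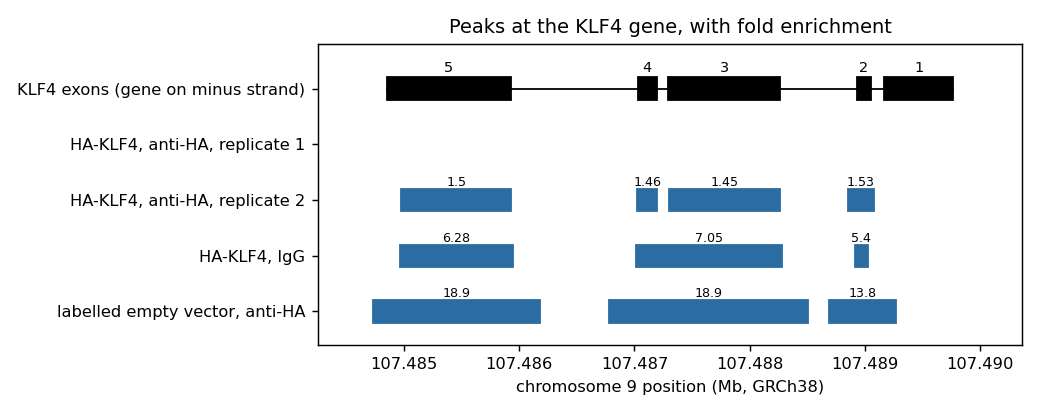
Peaks (blue bars, with fold enrichment above) along the KLF4 gene on chromosome 9 (Mb, GRCh38) in the 4 libraries, below its 5 exons (black). Peaks follow exons 2 to 5 in replicate 2, the IgG control and the library labelled empty vector, with highest folds of 1.53, 7.05 and 18.9, and replicate 1 has none. Exon 1 is covered in part in the library labelled empty vector alone.

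By q-value the strongest peak of either control was on KLF4 exons, at rank 1 in both lists. By fold other kinds of sequence came ahead of it, and in the IgG control the highest was on SNORD3A, a U3 small nucleolar RNA gene (chromosome 17, 19188046 to 19188167, fold 26.6), and SNORD3B-2 had 16.1. The others of its 5 highest lay between annotated genes on chromosome 17 (fold 19.4), on a sequence outside the chromosomes used (14.6) and in CCDC200 (14.5). In the library labelled empty vector the highest peak was at the 5' end of PAXBP1 (chromosome 21, 32771601 to 32772171, fold 22.1), followed by the end of chromosome 12 (19.1), both KLF4 peaks at 18.9 and an unplaced sequence (18.1).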

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

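The tests of KLF4 cDNA and of a wrong label, and the distances of peak edges from exons, were chosen after the results were seen. The tests of tandem repeats were written before their own results but after the sequences of the strongest regions had been read, from which the word CACCC was taken. The edge distances were measured after the cDNA test had left the question open, and bounds drafted for them with the values already known were withdrawn, so they are given as values without a verdict.

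KLF4 exon peaks had a highest fold of 7.05 in the IgG control, made from cells given the KLF4 vector, and of 18.9 in the library labelled empty vector, whose label gives no source of it. In HA-KLF4 replicate 2 it was 1.53, but these folds are not comparable, since the background of each list is not given and vector DNA in it would lower the fold at KLF4. A wrong label on an HA-KLF4 anti-HA library enriched like the 2 replicates is argued against. Only 8.0% of the peaks of the library labelled empty vector (upper limit 10.1%) lay in shared HA-KLF4 regions, where at least 50% was required. That bound was set after the results were seen, and a weakly enriched HA-KLF4 library could also fall below it, so other forms of a wrong label stay open. Of 253 IgG peaks, 123 overlapped a peak of the library labelled empty vector. Reads of KLF4 cDNA may account for the KLF4 exon peaks, but the test of that, which required both controls, left this open. The excess of exon over intron coverage was 0.666 in the IgG control, above the bound of 0.3. It was 0.223 in the library labelled empty vector, between the bounds of 0.1 and 0.3, because its wide peaks run into introns. Plasmid reads in the transfected cells also stay open: coding exceeded intron coverage by 0.931 in replicate 2 and by 0 in replicate 1, and the prediction required both replicates and no such peak with the empty vector. How KLF4 sequence came into that library was not tested, and no biological explanation was tested.

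Strong regions in tandem repeats are a further pattern. Repeat copies missing from the reference were predicted to give summits as often without CACCC as with it. Of 71004 tandem-rich windows of 400 bp without CACCC, 1.95% held a shared summit (upper limit 2.06), compared with 23.6% of 9504 windows with 5 or more. That prediction was not met. Windows outside tandem repeats were not compared, so whether tandem repeats as such raise signal cannot be told. Those 71004 windows also held 78 IgG summits and 93 of the library labelled empty vector, and the 9504 held 3 and 9. Base composition alone was predicted to give no rise with CACCC. With GC and the count of CCCCA in the model, the log odds rose by 0.436 (0.414 to 0.458) per doubling of the CACCC count plus 1, so that prediction was not met. The word CACCC was taken from the strongest of these regions, which stayed in the model, while CCCCA was not. The result therefore cannot decide between composition and the CACCC sequence. GC content contributed to the model as well, at 1.21 per 10 points. Among windows of 55 to 70% GC the shares with a shared summit were closer, at 12.6% of 6068 without CACCC and 28.8% of 4787 with 5 or more. Those 6068 windows held 0 IgG summits and 4 of the library labelled empty vector, and the 4787 held 3 and 8. These control counts are small, but they run the other way from those of all windows. Missing copies, those of CACCC repeats in particular, stay open without the inputs, and clustered KLF4 sites remain a hypothesis that came from these same regions.

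Promoter concentration was set against a general tendency of promoters to give peaks with this antibody. In the library labelled empty vector 3.0% of peaks were at promoters (upper limit 4.43), below the 17.2% of HA-KLF4 regions, which argues against that explanation as far as the label holds. The IgG share of 14.6% (10.8 to 19.5) includes 17.2%, so a promoter bias of recovered chromatin as such is not excluded.

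Peaks on sequences outside chromosomes 1 to 22, X and Y were more numerous in both HA-KLF4 replicates, 81 and 156, than in the controls, 67 and 62, although they were 0.0726% and 0.117% of those lists and 20.9% and 7.19% of the control lists.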

How the results depend on the processing

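Of 103 values of the main results under 22 alternatives, 90 kept their direction and side of the threshold, or their count within 1.5 times. The 3 alternatives named in the methods as chosen after seeing the data changed none of these. Gene lists were scored here by their number alone, so a change in which lists were called could count as kept. The 4 lists below other genes with GC and CpG in the model counted as kept, although FOX and SOX genes had taken the place of the liver and blood lists. With the strongest 25% of regions the lists called were also largely others. At −log10 q of at least 10 the peaks numbered 53656 and 65544 in the HA-KLF4 replicates, 171 in the IgG control and 132 in the library labelled empty vector (484 at 5 or more). Shared regions fell to 47631, regions outside controls to 47601 and KLF4 exon peaks of replicate 2 to 1, by construction, since fewer peaks were used. The overlap of the library labelled empty vector with shared regions was 6.93% (permutation p = 0.14). Lists above other genes numbered 4 at −log10 q of at least 5 or 10 and with promoters of 500 bp, instead of 8, and 1 of the 6 that could be fitted with GC and CpG in the model. Odds ratios were followed for the lists called with all regions by the exact test or the logistic model. Calls gained by other lists, such as WNT ligands with the strongest 25% of regions, are not among them. A change of sign was counted as that alone, even where a call came with it, as for FOX genes with the strongest 25%. Of 180 such odds ratios, 136 kept their call, 26 lost it, 2 gained it and 16 changed sign. On the log2 scale these were, with the strongest 25% of regions, ribosomal proteins −1.11, proteasome −1.33, ZNF −0.59, HOX −0.57, FOX 1.66 and SOX 0.59. At −log10 q of at least 10 they were proteasome −0.70, ZNF −0.35 and FOX 0.57. With promoters of 5000 bp FOX was 0.64 and SOX 0.27, and with any overlap 0.33 and 0.55. HOX was −0.0445 with promoters of 500 bp, the liver list 0.10 with GC and CpG, and FOX 0.31 without replicate 2. Without replicate 1 FOX kept its sign, at −0.14. Other causes were not tested. Folds of named genes moved by more than the SD for ADAMTS2 (2.56) and KLF13 (5.98) without replicate 2, for ADAMTS5 without replicate 1 (5.10), for KLF13 (7.501), ADAMTS5 (3.29) and ENG (9.38) with promoters of 500 bp, and for COMP (18.1) and OR6B3 (6.72) with 5000 bp. Genes without a promoter region under an alternative were left out. No paired analysis was possible because the groups share fewer than 2 replicate numbers. Unknown read depth limits every count.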

Other observations

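The count from the strongest regions was chosen before the data were examined, whereas small RNA genes were tested after the IgG peaks had been seen. When occupancy was counted from the 25% of regions with the highest fold, the lists that stood out were largely others. FOX genes (29 of 52, 55.8% against 28.5% of other genes, adjusted p = 0.00072), WNT ligands (12 of 19, adjusted p = 0.010), chondrocyte transcription factors (17 of 35, adjusted p = 0.048) and KLF and SP factors (14 of 26, adjusted p = 0.030) were above other genes by Fisher's exact test, beside TGF-beta and BMP signalling (21 of 36, adjusted p = 0.0023) and the circadian clock (11 of 16, adjusted p = 0.0069). By the same exact test, ribosomal proteins (13 of 85, adjusted p = 0.027) and ZNF-named genes (107 of 508, adjusted p = 0.0014) were below, although both were above with all regions. FOX genes were below other genes when GC and CpG were in the model for all regions (adjusted p = 0.0056, n = 19654 genes). The strongest regions are also the richest in GC, and no such model was run on them, so composition stays open for these lists. Olfactory receptors (0 of 381) and keratins (7 of 55, exact test, adjusted p = 0.030) were below in both counts.

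IgG peaks were frequent on small RNA genes. Of 253 IgG peaks, 25 (9.88%, Wilson interval 6.78 to 14.2) overlapped such a gene, against a mean of 0.162 peaks after shifting (permutation p = 0.001, the smallest possible). These included RNU1-1, RNU4-2, RNU5A-1 and RNU12, which encode spliceosomal RNAs, and SNORD3A. In the library labelled empty vector 12 of 800 peaks overlapped such a gene (1.5%, 0.860 to 2.60). Shifting gave a mean of 0.777 peaks and a maximum of 5 (permutation p = 0.001), so the excess was not limited to IgG.

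Peaks found in replicate 2 alone numbered 36247. Their median fold was 3.30, and 19.2% held the KLF core against 5.69% of flanks, a ratio of 3.38 (3.26 to 3.51), where noise without the sequence had been predicted to stay at or below 1.1.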
